A study of Drosophila melanogaster with 8 samples.

How the data were processed

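RNA was sequenced from heads and thoraxes of mated females of 2 fly strains, with 4 libraries per strain and 60 flies per library. Per the labels' protocols, flies were kept at 25 °C, RNA was extracted with a column kit, all samples were prepared at the same time, and poly(A)-selected libraries were read as read pairs on an Illumina HiSeq instrument. Per the submitters' processing notes, the tools were bcl2fastq, FastQC, TopHat2 2.0.7 and DESeq2, with genome build BDGP5; the step each did, the counting program, its treatment of strand and shared reads, and the annotation are not given in the sources used here.

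The deposited table held the authors' comparison of the strains, with no column for any single library. Per the file headers, its columns were a mean over libraries, a log2 fold change, the standard error (SE) of that log2 fold change, a p-value and an adjusted p-value. The mean is a signal on the scale of normalized read counts as deposited, and its unit rests on the name of the column and on its values. The deposited p-value equalled the 2-sided normal p of fold change over SE to within 4.1e-15, so it is the p of a Wald test. The authors' adjusted p-values matched Benjamini-Hochberg adjustment over about 13322 tests. SE in the deposited table never exceeded 0.42 and fell at the lowest means, with a median of 0.17 at means under 1 and 0.41 at means from 3 to 10, a shape that fold changes shrunken toward 0 have; a prior is not given in the sources used here, and fold changes of genes with low counts may be understated. The direction of the fold change was read from the order of the strain names, as higher in Dahomey where positive; the headers do not state it.

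The table had 14944 rows, of which 633 had a mean of 0, 13395 had a p-value and 916 had a fold change and SE without a p-value. These 916 rows stayed without a p. They were left out of counts of genes that passed, and 10 p-values listed as 0 were kept so. Gene IDs numbered 14701, and 205 of them stood on more than 1 row. Another 265 rows with a mean of at least 10 shared all their values with a row of another ID, in 129 blocks, which marks genes counted on the same reads. Counts over the whole table are counts of rows as deposited. Lists, arms and neighbours used 1 row per gene ID, that of the highest mean, and 1 row per block of shared values, which gave 13065 genes with a p-value. IDs were matched to symbols through a table of gene IDs, and 14367 of 14701 matched. Chromosome arms, exon lengths and the order of neighbouring genes came from an annotation of the BDGP6 assembly, looked up by gene ID. Because the authors' build was BDGP5, no coordinates are given.

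Before the data were examined, counts per library had been assumed, with a count model as the main test. The unit turned out to be that of a finished comparison, so the authors' adjusted p under 0.05 took the place of that model. Strain-limited genes, which need the counts of each library, were not analysed here. Mean CPM was taken as the mean over the sum of all means, 112781736, with each block of shared values counted once; 5 CPM then equals a mean of 564. Depth per library, the spread between libraries and possible repeats of a library could not be checked, and nothing in the labels says that the libraries of a strain came from separate cultures, so p-values measure only the spread between these samples. As a guide to precision, the median SE was 0.082 for rows with a mean of at least 1000, and SE differed between genes of the same mean.

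The 34 gene lists were fixed before the data were examined, from general knowledge of fly genes. Each of the 32 with at least 5 members that had a p was compared with all other genes by limma's cameraPR (limma 3.58.1, R 4.3.3) on the Wald statistic, 2-sided, with a preset correlation of 0.01, and p-values were adjusted over the lists by the Benjamini-Hochberg method. For counts adjusted over the list alone, the same adjustment was applied to the deposited p-values of the members. Shares by arm were compared by a chi-square test. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

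Genes named in the text followed a rule set beforehand. They were the 10 highest and 10 lowest fold changes among genes with an adjusted p under 0.05, a mean of at least 5 CPM and a symbol other than a bare annotation number; 2 higher and 2 lower genes with such a number; the 5 smallest p-values, ranked by fold over SE where p was listed as 0; up to 2 higher and 2 lower members of each list by smallest p, or in cell-type lists with fewer than 2 members past the threshold the 2 of highest mean; and roX1 and roX2. The rule also asked that the libraries of the strains not overlap, which could not be applied. Genes named only in the closing part on other observations, and among the results looked at more closely, were chosen after their values were seen. The same holds for the midgut genes named without a p-value.

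Alternatives were a minimum of 5 CPM, 1 row per gene, a p from fold and SE where none was given, adjustment recomputed over the rows, an adjusted p under 0.01, and for lists ranks, a correlation of 0.05 and 10000 random lists matched on the mean. The gene step was tested on simulated fold changes built on the SE of the 13065 genes of the Dahomey and Oregon R comparison. Changed genes were picked among those with a mean of at least 5 CPM. Of 100 given a log2 fold change of 0.3, 67% were recovered, and of 100 given 1.0, 100%, while 0.0855% of unchanged genes passed. The noise was normal with the same SE that the test then used, so few false calls were built in. These rates check the steps alone and cannot show whether the deposited SE are right. The list step used independent standard normal statistics, where 3 of 3 shifted lists were recovered and 0 of 29 others were called. The real statistics spread more widely and members may be correlated, so this gives no rate of false list calls in the real table.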

Results

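Whole-transcriptome RNA sequencing compared adult females of 2 laboratory strains of Drosophila melanogaster, Dahomey and Oregon R. The RNA came from heads and thoraxes together, with abdomens left out, of mated flies aged 10 days. Each strain had 4 libraries, and each library held 60 flies. The comparison asked which genes differed in transcript abundance between the strains at this age, in tissue that includes brain, eye, flight muscle and some fat body. The data were the authors' own DESeq2 comparison, a table with 1 mean normalized read count, 1 log2 fold change with its standard error (SE) and 1 adjusted p per entry. Values per library were not used here, so errors are the authors' SE and the depth of each library is unknown. The submitters stated 90000000 reads per sample, and the mean normalized counts summed to 112781736. Positive fold changes were read as higher in Dahomey, from the order of the strain names in the table's name; the column headers do not give the sign, and with the reverse order all directions given here would turn together.

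The named genes with the highest fold changes in Dahomey included a lectin gene, a chaperone gene, an antiviral gene and genes of detoxification and taste. In the authors' deposited table, lectin-28C, a C-type lectin (FBgn0040099, arm 2L), had a log2 fold change of 3.66 ± 0.18 (SE; adjusted p = 1.08e-85), and Hsc70-2, a constitutive member of the heat-shock chaperone family (FBgn0001217, arm 3R), had 3.62 ± 0.19. GstO3, an omega-class glutathione S-transferase on arm 3L, was 6.97-fold higher in Dahomey in the authors' deposited table, with a log2 fold change of 2.80 ± 0.071. Nazo, an antiviral effector gene of the STING pathway, and ppk28, which encodes the ion channel of water-taste neurons, each had a log2 fold change of 2.57, with SE of 0.13 and 0.077 in the authors' deposited table. The actin-binding protein genes Unc-115b and Unc-115a lie near each other on arm 3R with p24-2, a cargo receptor gene of the early secretory pathway; the authors' deposited table gave them log2 fold changes of 2.62 ± 0.081, 2.27 ± 0.084 and 2.26 ± 0.076. Acox57D-d, a peroxisomal acyl-CoA oxidase gene, and Ugt35C1, a UDP-glycosyltransferase gene, were higher in Dahomey by 2.28 ± 0.096 and 2.01 ± 0.14 on the log2 scale in the authors' deposited table. Among genes known by an annotation number alone, the neighbours CG10154 and CG10725 on arm 3L stood out in the authors' deposited table, at 8.32 ± 0.28 and 5.29 ± 0.14.

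The named genes with the highest fold changes in Oregon R included genes of the digestive tract, a cuticle gene and cytochrome P450 genes. According to the authors' deposited table, the larval cuticle protein gene Lcp1 (FBgn0002531, arm 2R) had a log2 fold change of -8.15 ± 0.14, a 284-fold difference, and the digestive lysozyme genes LysC and LysD on arm 3L had -8.06 ± 0.13 and -7.74 ± 0.13. The gut serine protease gene Jon99Ci (FBgn0003358, arm 3R) had -6.47 ± 0.12 and Cyp6a17, a cytochrome P450 gene with a known role in temperature preference (FBgn0015714, arm 2R), had -5.40 ± 0.10 in the authors' deposited table. These 5 genes also had the largest ratios of fold change to SE among genes with a p-value, which the authors' deposited table listed as 0 for them. Drsl4, a drosomycin-like peptide gene, had -3.91 ± 0.14, Ugt37A3 had -3.49 ± 0.15 and Cyp6a14 had -3.07 ± 0.11 in the authors' deposited table. Of the trypsin genes on arm 2R, 4 near-identical copies were lower in Dahomey, with deltaTry at -3.18 ± 0.16, gammaTry at -3.10 ± 0.14, CG30031 at -3.21 ± 0.16 and CG30025 at -3.15 ± 0.15 in the authors' deposited table. LysC and LysD are also such copies, whose reads the counting could split, so the value of each copy alone is uncertain.

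**Figure D1:**
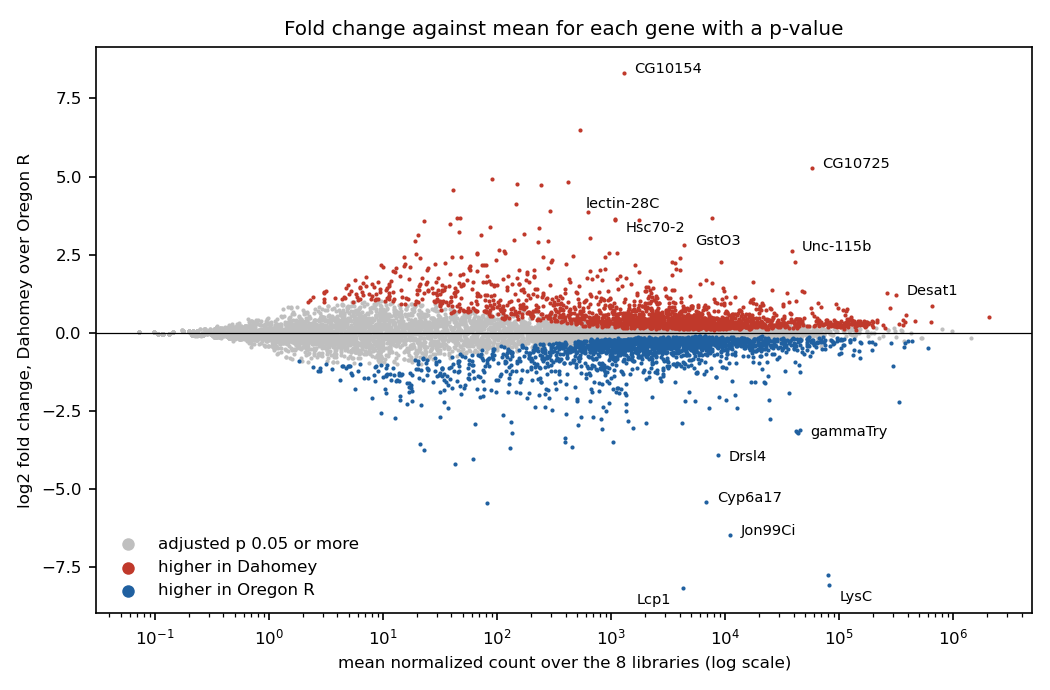
Log2 fold change (Dahomey over Oregon R) against the mean normalized count (log scale), 1 point per gene with a p-value in the authors' deposited table. Red points were higher in Dahomey and blue points higher in Oregon R at an adjusted p under 0.05; no error bars are drawn. The named genes include CG10154 at 8.32 and Lcp1 at -8.15.

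Across the table, 3939 of 13395 entries with a p-value differed between strains at the authors' DESeq2 adjusted p under 0.05, which is 29.4% of them. The directions were even, with 1970 entries higher in Dahomey and 1969 higher in Oregon R. Most differences were small: the median absolute log2 fold change of the entries that passed was 0.42, and 695 of them, or 17.6%, differed by at least 2-fold. Of these 695, 346 were higher in Dahomey and 349 in Oregon R. With a mean of at least 5 CPM (counts scaled to the table's total) required, 245 entries differed by at least 2-fold. A further 916 entries had a fold change and no p-value, and none of them is included in these counts.

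Detoxification genes differed in both directions, and among cytochrome P450 genes that passed more were higher in Oregon R than in Dahomey. Cytochrome P450 enzymes oxidise hormones, plant toxins and insecticides. Of 76 list members with a p-value 14 were higher in Dahomey, 32 were higher in Oregon R and 30 did not pass (15 and 34 when adjusted over the list alone). The list took every symbol of Cyp and a digit, which also fits the cyclophilin genes Cyp1 and Cyp40. Its counts and tests are therefore not those of P450 genes alone. Besides Cyp6a17, the authors' deposited table gave Cyp4p2 a log2 fold change of -3.65 ± 0.13, and in the other direction Cyp6a23 had 1.19 ± 0.10 and Cyp12c1 had 0.69 ± 0.083. Glutathione S-transferases, which conjugate electrophilic compounds to glutathione, split evenly, with 12 of 36 genes higher in Dahomey, 12 higher in Oregon R and 12 that did not pass (12 and 13 when adjusted over the list alone). The authors' deposited table placed GstO1 with GstO3 among the higher genes, at 1.35 ± 0.13, and GstD3 and GstE6 among the lower ones, GstD3 at -2.70 ± 0.11 and GstE6 with a 2.0-fold difference. UDP-glycosyltransferases attach sugars to small lipophilic molecules, and 6 of 30 genes were higher in Dahomey and 10 in Oregon R (7 and 11 when adjusted over the list alone). Ugt35A1 had 1.12 ± 0.065 and Ugt37A1 had -3.70 ± 0.31 in the authors' deposited table. Among alcohol dehydrogenases and esterases, which break down alcohols and esters, 4 of 16 genes were higher in Dahomey and 5 in Oregon R (5 and 7 when adjusted over the list alone). Est-P, the neighbour and paralog of the male esterase gene Est-6, had 3.36 ± 0.17 and Aldh 0.45 ± 0.10, against -0.83 ± 0.10 for Sodh2 and -0.49 ± 0.077 for alpha-Est10, in the authors' deposited table. Of the antioxidant and redox genes, 7 of 26 were higher in Dahomey and 5 in Oregon R, the same counts as when adjusted over the list alone. The authors' deposited table held Gclm, a subunit of the enzyme of glutathione synthesis, at 0.48 ± 0.079, Prx4 at 0.39 ± 0.075, the metallothionein gene MtnA at -0.45 ± 0.053 and the mitochondrial superoxide dismutase gene Sod2 at -0.27 ± 0.057.

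Most ribosomal protein genes were higher in Dahomey, and of the nuclear genes of oxidative phosphorylation that passed, most were lower. Of 86 genes for cytosolic ribosomal proteins, 65 were higher in Dahomey, 1 was lower and 20 did not pass (67 and 2 when adjusted over the list alone), with a median log2 fold change of 0.29. RpL11 had 0.50 ± 0.054 and RpL34b 0.42 ± 0.042 in the authors' deposited table, and the exception, RpL7-like, had -0.24 ± 0.079. Of 89 nuclear genes for the respiratory chain and ATP synthase, 42 were lower in Dahomey, 3 were higher and 44 did not pass (44 and 4 when adjusted over the list alone), with a median log2 fold change of -0.19; as a list they passed with a preset correlation of 0.01 (adjusted p = 0.00123 by limma) and not with 0.05 (adjusted p = 0.203). SdhA, of complex II, had -0.82 ± 0.089 and Cyt-c-p, a cytochrome c gene, had -0.67 ± 0.073 in the authors' deposited table; the complex I genes ND-13B and ND-B12 went the other way, at 0.76 ± 0.058 and 0.20 ± 0.059. Genes of the mitochondrial genome itself gave no call in the authors' DESeq2 test: 28 of 37 had no p-value, and 0 of the other 9 passed either with the adjusted p or with an unadjusted p under 0.05. Genes of glycolysis and sugar storage split evenly, with 9 of 25 higher in Dahomey and 9 higher in Oregon R (10 and 9 when adjusted over the list alone). The authors' deposited table had Tps1, which makes the blood sugar trehalose, at 0.92 ± 0.070 and Pgd, of the pentose phosphate pathway, at 0.73 ± 0.071, against Treh, which splits trehalose, at -0.73 ± 0.076 and Gapdh1 at -0.65 ± 0.068. Muscle genes went both ways as well, with 12 of 33 higher in Dahomey and 8 in Oregon R (13 and 8 when adjusted over the list alone) and a median of 0.14. In the authors' deposited table the actin gene Act79B had 0.53 ± 0.068. Mlc-c, a cytoplasmic myosin light chain gene that the list includes but that does not mark muscle, had 0.40 ± 0.041. The flight-muscle troponin C gene TpnC4 had -0.77 ± 0.10 and the arginine kinase gene Argk1 had -0.55 ± 0.052.

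In each of the immune and stress lists, members differed in both directions. Of 13 antimicrobial peptide genes with a p-value, 7 were higher in Dahomey and 3 in Oregon R, the same counts as when adjusted over the list alone. In the authors' deposited table, Def, the defensin gene, had 1.00 ± 0.14 and Drsl3 had 3.14 ± 0.40, whereas the cecropin gene CecA2 had -4.20 ± 0.37; Drsl3 and CecA2 had low mean counts, at 20.2 and 42.7. Bomanins and related peptides, induced through the Toll pathway, were split, with 3 of 8 higher in Dahomey (BomT2 at 0.70 ± 0.15 and BomS4 at 0.47 ± 0.12 in the authors' deposited table) and 2 in Oregon R (BomS2 at -0.68 ± 0.15 and IM33 at -0.40 ± 0.089). Among genes for immune recognition and signalling, 9 of 40 were higher in Dahomey and 8 in Oregon R (12 and 8 when adjusted over the list alone). PGRP-SD, a peptidoglycan sensor, had 1.47 ± 0.12 and the protease gene psh, of the Toll pathway, 0.88 ± 0.11, against -1.31 ± 0.11 for PGRP-SC2, an enzyme that degrades peptidoglycan, and -1.21 ± 0.21 for the prophenoloxidase gene PPO3, in the authors' deposited table. Of the genes for RNA interference and antiviral defence, 4 of 16 were higher in Dahomey and 1 in Oregon R (5 and 1 when adjusted over the list alone). The authors' deposited table had pst, a gene at which natural variants alter resistance to a virus, at 0.82 ± 0.071 beside Nazo, and loqs, a partner of Dicer, at -0.23 ± 0.092. Turandot stress peptides and JAK-STAT genes gave 2 higher and 1 lower of 11 with a p-value: the JAK-STAT receptor genes et and dome had 0.57 ± 0.076 and 0.26 ± 0.079, and TotX had -1.63 ± 0.18, in the authors' deposited table. Heat-shock and chaperone genes gave 2 higher and 4 lower of 14. Hsc70-3, the chaperone of the endoplasmic reticulum, had 1.03 ± 0.10, and Hsp67Bc and Hsc70-1 had -0.89 ± 0.16 and -0.30 ± 0.059 in the authors' deposited table. For the Bomanin, Turandot and heat-shock lists the counts were unchanged when adjusted over the list alone; 9 of 22 antimicrobial peptide genes, 8 of 16 Bomanin genes and 12 of 26 heat-shock genes had no p-value.

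Digestive genes with a p-value held some of the largest differences toward Oregon R, and smaller ones toward Dahomey. Of 37 midgut genes with a p-value, 8 were higher in Dahomey and 12 in Oregon R, the same counts as when adjusted over the list alone. Against the low values of LysC, LysD, Jon99Ci, gammaTry and deltaTry, the trypsin genes betaTry and epsilonTry, also on arm 2R, had 0.81 ± 0.066 and 1.37 ± 0.12 in the authors' deposited table. The midgut members with a p-value had a median log2 fold change of only -0.04 but a mean of -0.80, and 32 of the list's 69 genes had no p-value. Members without a p-value had large fold changes both ways. Mal-A4 had 4.81 ± 0.29 and Jon25Bi 3.02 ± 0.21, against -8.97 ± 0.17 for LysB and -5.02 ± 0.18 for LysE, in the authors' deposited table. Over all 69 genes, the SE were a median of 1.82 times those of genes with the same mean count. Genes of lipid metabolism and fat body gave 6 higher and 4 lower of 18. Desat1, a fatty acid desaturase of pheromone and membrane lipid synthesis, had 1.23 ± 0.11 and Lip3, a lipase induced by fasting, had -1.58 ± 0.24 in the authors' deposited table. The larval fat-body genes Fbp2 and Lsp1alpha had 1.60 ± 0.30 and -1.81 ± 0.42 there, from mean counts of 46.2 and 10.5 in the authors' deposited table. Of the yolk protein genes, which fat body and ovary express, Yp1 was higher in Dahomey, at 0.52 ± 0.16 in the authors' deposited table, and Yp3 and Yp2 had no p-value. In insulin and TOR signalling, 4 of 25 genes were higher in Dahomey and 4 in Oregon R. The insulin-like peptide genes were themselves divided in the authors' deposited table: Ilp6, made in fat body, had 1.46 ± 0.10 and Ilp7, made in neurons, 1.27 ± 0.14, while Ilp3, made in brain cells, had -0.97 ± 0.15, and the adaptor gene Lnk had -0.24 ± 0.071. Ecdysone and juvenile hormone genes gave 2 higher and 6 lower of 24. Both higher genes act on juvenile hormone, jhamt in its synthesis at 1.11 ± 0.17 and Jheh3 in its breakdown at 0.84 ± 0.088, and Jheh2 and JhI-26 had -0.38 ± 0.058 and -0.42 ± 0.090, in the authors' deposited table. The counts for lipid, yolk, insulin and hormone genes were unchanged when adjusted over the list alone.

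Most phototransduction, pigment and neuron genes that passed were lower in Dahomey. Phototransduction genes gave 13 lower and 4 higher of 30 (14 and 5 when adjusted over the list alone), with a median of -0.16. The gene inaF-B, needed for the TRP channel of photoreceptors, had -1.57 ± 0.079 and the rhodopsin kinase gene Gprk1 had -0.61 ± 0.095, whereas the opsin genes Rh6 and Rh2 had 0.82 ± 0.11 and 0.62 ± 0.091, in the authors' deposited table. Eye pigment and body colour genes gave 8 lower and 3 higher of 24 (10 and 4 when adjusted over the list alone). The authors' deposited table had the pigment genes cd and st at -0.92 ± 0.12 and -0.54 ± 0.11, se, which acts in the synthesis of red pigment, at 0.90 ± 0.086, and yellow-d at 0.90 ± 0.11. Neuron and glia genes gave 8 lower and 1 higher of 22, unchanged when adjusted over the list alone. ChAT, the enzyme that makes acetylcholine, had -0.95 ± 0.10 and the synapsin gene Syn had -0.50 ± 0.082, and the midline-glia gene wrapper had 0.60 ± 0.12, in the authors' deposited table. Neuropeptide genes went both ways, with 7 of 26 higher and 8 lower (7 and 9 when adjusted over the list alone): Mip and Nplp4 had 0.83 ± 0.092 and 1.56 ± 0.22, and Nplp3 and the clock-neuron peptide gene Pdf had -1.22 ± 0.093 and -0.48 ± 0.12, in the authors' deposited table. Of the circadian clock genes, 4 of 15 were higher in Dahomey and 1 lower, the same as when adjusted over the list alone; cyc and cwo, both transcription factors of the clock, had 0.46 ± 0.051 and 0.45 ± 0.084 and the photoreceptor gene cry had -0.58 ± 0.082 in the authors' deposited table.

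Among odorant-binding protein genes that passed, nearly all were lower in Dahomey; most genes of this list and of the odorant, gustatory and ionotropic receptors did not pass. Of 36 odorant-binding protein genes, 11 were lower and 1 was higher (12 and 1 when adjusted over the list alone). Obp44a, made in glia, had -1.92 ± 0.11 and Obp56h -2.17 ± 0.21, and the exception, Obp56f, had 1.36 ± 0.32 from a mean count of 32.8, in the authors' deposited table. Of 177 chemosensory receptor genes, 19 were higher in Dahomey, 9 were lower and 149 did not pass (15 and 8 when adjusted over the list alone). The odorant receptor genes Or85f and Or63a had 1.57 ± 0.22 and -1.45 ± 0.11, and the gustatory receptor genes Gr98a and Gr61a, the latter a sugar receptor, had 1.83 ± 0.26 and -1.97 ± 0.22, in the authors' deposited table. Cuticle protein genes gave 15 higher and 15 lower of 117, unchanged when adjusted over the list alone. Besides Lcp1, the authors' deposited table gave Cpr51A -2.23 ± 0.12, and Cpr62Bb and Cpr47Ef had 1.85 ± 0.078 and 1.81 ± 0.14.

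Markers of tissues that the dissection should leave out, and of males, were examined as lists. Of 32 ovary and eggshell genes only 6 had a p-value, 1 of which passed: grk, the signal that sets the axes of the egg, at 0.32 ± 0.12 in the authors' deposited table. The most abundant members were osk, at a mean normalized count of 11153 with a log2 fold change of -0.36 ± 0.37 and no p-value, and bru1, at 11126 with -0.31 ± 0.14 and an adjusted p of 0.0894, in the authors' deposited table. The SE of the ovary genes were a median of 3.61 times those of genes with the same mean. Of 29 testis and accessory gland genes 3 were higher in Dahomey and 0 lower, among them can at 2.07 ± 0.29 and fzo at 0.98 ± 0.30, from mean counts of 57.5 and 35.8 in the authors' deposited table. Genes of male dosage compensation served as a check of sex: roX1 had a mean count of 513 and a log2 fold change of -0.29 ± 0.12, roX2 a mean of 25.2 and -0.78 ± 0.39, and msl-2 a fold change of -0.01 ± 0.092 in the authors' deposited table. In the authors' DESeq2 test 0 of these 3 passed, and 2 had an unadjusted p under 0.05. Hemocyte genes gave 1 higher and 5 lower of 14 (1 and 8 when adjusted over the list alone), with srp at 0.34 ± 0.10, lz at -0.78 ± 0.12 and NimC2, a phagocytosis receptor gene, at -0.83 ± 0.15 in the authors' deposited table. Salivary gland and foregut genes gave 0 calls among 9 in the authors' DESeq2 test, with or without adjustment; fkh had 0.03 ± 0.12 and Sgs1 0.14 ± 0.29 in the authors' deposited table. Ovary, testis, dosage compensation and salivary counts were the same when adjusted over the list alone.

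**Figure D2:**
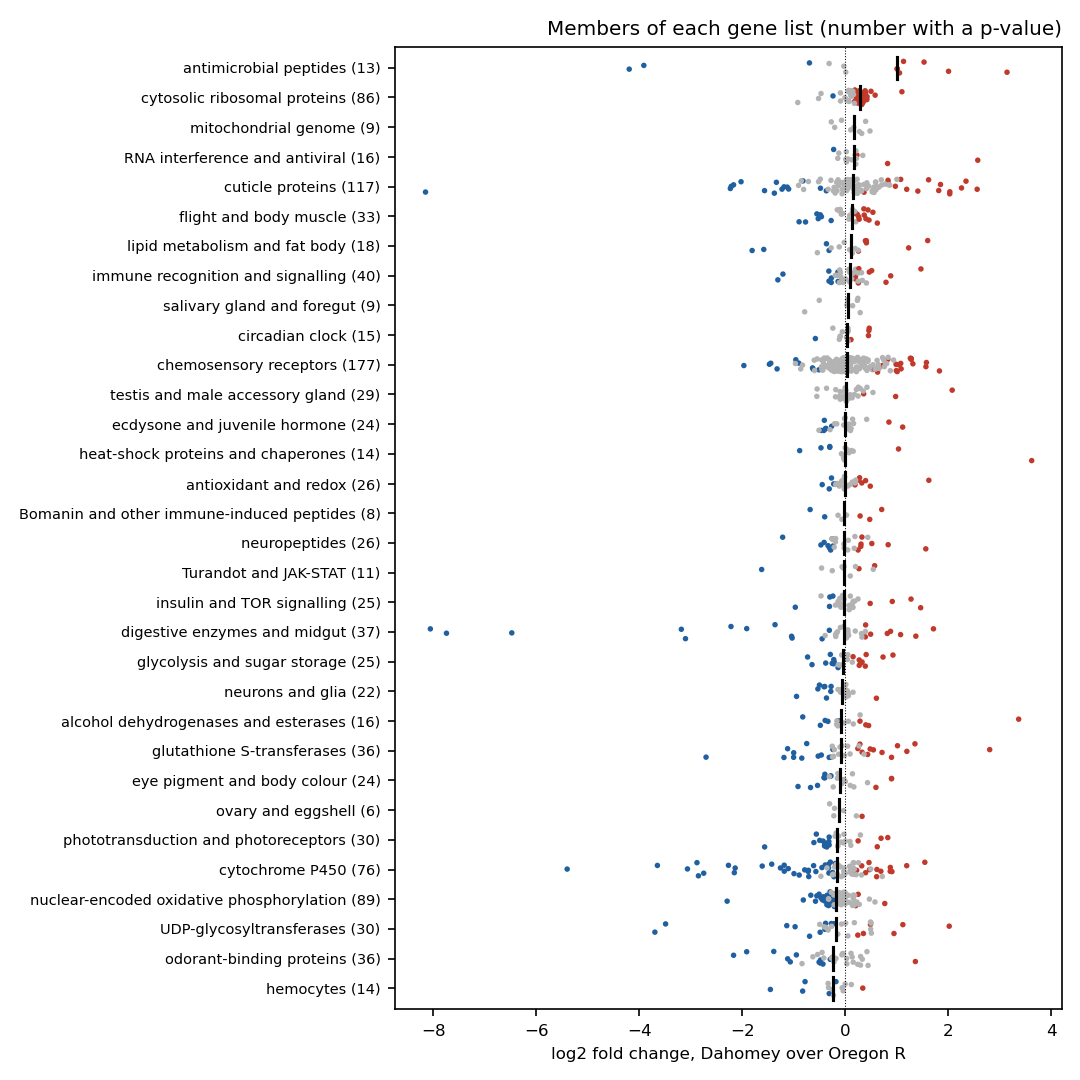
Log2 fold change (Dahomey over Oregon R) of each member with a p-value, for the 32 lists with at least 5 such members; red and blue points passed an adjusted p under 0.05 in either direction, grey points did not, and the black bar is the list's median. Ribosomal protein genes lie to the right, with a median of 0.29, and oxidative phosphorylation genes to the left, with a median of -0.19.

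Set against all other genes, 4 of 32 lists differed between strains as a whole. In limma's competitive test with a preset correlation between genes of 0.01, ribosomal protein genes were higher in Dahomey (adjusted p = 2.39e-11). Midgut genes (adjusted p = 5.61e-14), the cytochrome P450 list (adjusted p = 1.06e-10) and oxidative phosphorylation genes (adjusted p = 0.00123) were higher in Oregon R. The P450 list, set by symbol, also fits the cyclophilin genes Cyp1 and Cyp40. With ranks in place of the test statistic, the adjusted p was 0.708 for midgut and 0.0949 for P450 genes. With the list's median set against random lists matched on the mean, it was 0.486 for midgut and 0.00128 for P450 genes. Random lists were drawn gene by gene, so these p-values allow for no correlation between members. With a preset correlation of 0.05 the oxidative phosphorylation result had an adjusted p of 0.203, and the correlation could not be estimated without values per library. Antimicrobial peptide genes had a median of 1.00 but a mean test statistic below 0, at -1.32, and an adjusted p of 0.689; against matched lists they were higher in Dahomey (adjusted p = 0.00128). Antiviral genes (adjusted p = 0.063), phototransduction genes (adjusted p = 0.0656) and odorant-binding protein genes (adjusted p = 0.0834) did not pass. Phototransduction genes passed by ranks (adjusted p = 0.0343) and against matched lists (adjusted p = 0.0064), and odorant-binding protein genes with a minimum of 5 CPM (adjusted p = 0.0436) and against matched lists (adjusted p = 0.00128), all higher in Oregon R.

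Genes that differed lay on all chromosome arms in similar shares. By arm, the share of tested genes with an adjusted p under 0.05 was 31.2% on 2L, 30.2% on 2R, 29.7% on 3L, 29.1% on 3R and 28.6% on X. The small chromosome 4 had 18 of 84 genes, or 21.4% (95% Wilson interval 14.0% to 31.4%). A chi-square test over the arms, which treats genes as independent and serves as a description, gave p = 0.195. Among genes with a mean of at least 5 CPM, shares ran from 21.5% on chromosome 4 and 36.7% on X to 42.7% on 2L, with a chi-square p of 0.000143.

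**Figure D3:**
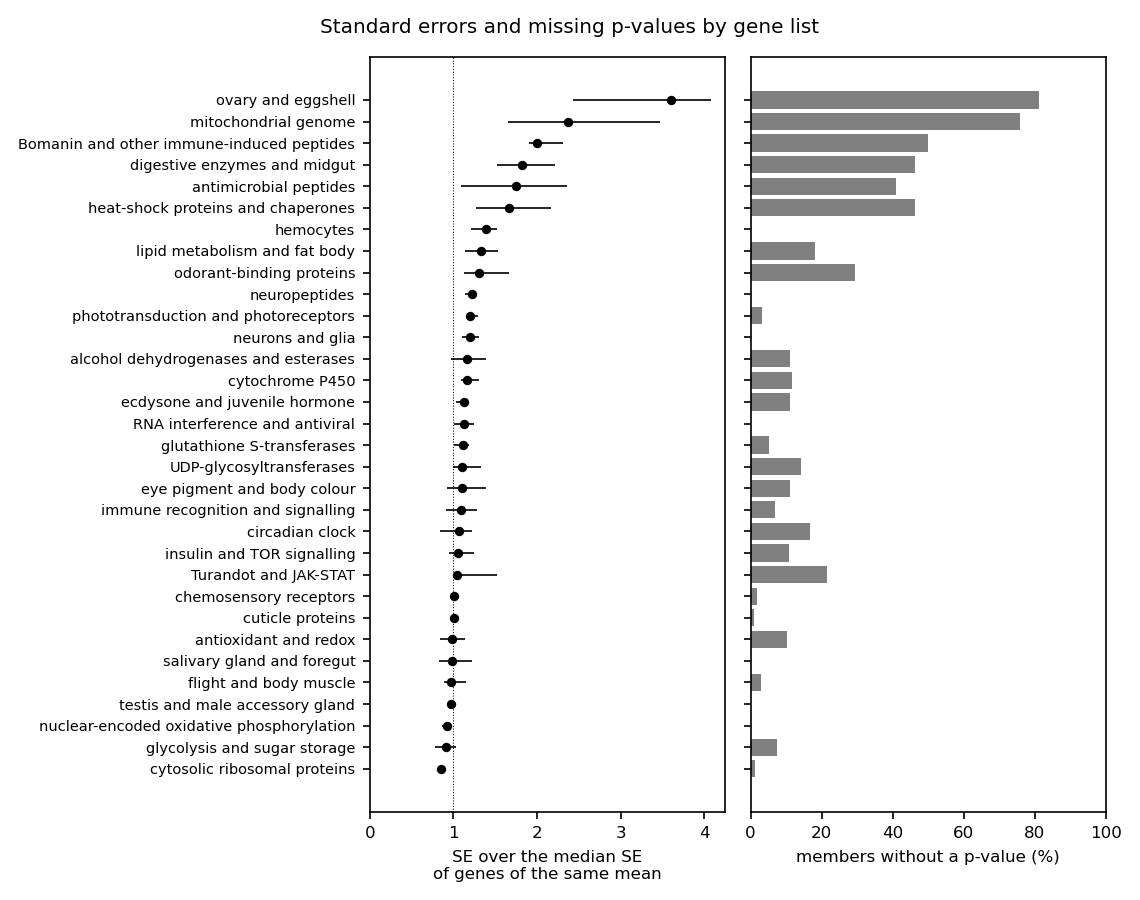
Left, the median ratio of a member's SE to the median SE of genes with the same mean count (points, with 95% bootstrap intervals over members); right, the percentage of members without a p-value, for the 32 lists with at least 5 members above 0. Ovary genes lie at 3.61 and 81.3%, and testis genes at 0.966 and 0%.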

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

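The tests of what lies behind the missing p-values were chosen, in the form given here, after these had been seen. A total of 916 entries with reads had a fold change and an SE but no p-value in the authors' deposited table, and no count of genes in the comparison uses them. They stood out as a signal outside the main measurement: with a p computed from fold and SE, 202 of them passed an adjusted p of 0.05, 94 higher in Dahomey and 108 higher in Oregon R, and 119 of these differed by at least 2-fold. Values of single libraries were not analysed here, so whether the fold and SE of such an entry rest on 1 library is open, and the 202 are not counted as genes that differed. The lysozyme gene LysB had a log2 fold change of -8.97 ± 0.17, LysE -5.02 ± 0.18, the sugar-cleaving maltase gene Mal-A4 4.81 ± 0.29, Bace 3.65 ± 0.17 and the protease gene Jon25Bi 3.02 ± 0.21 in the authors' deposited table. Among stress and immune genes, TotM had -2.38 ± 0.16 and the metchnikowin gene Mtk 2.35 ± 0.35, both without a p-value in the authors' deposited table.

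Genes without a p-value made up 81.3% of ovary and eggshell genes (Fisher's exact test, adjusted p = 1.14e-24) and 75.7% of the mitochondrial genome. The 3 yolk protein genes lay at 66.7%, Bomanin genes at 50%, midgut at 46.4%, heat-shock at 46.2% and antimicrobial peptide genes at 40.9%. The share was 6.4% of all entries above 0, and 0% of the testis, neuron and hemocyte lists. Low counts are argued against, since 0.0428% of genes with a mean under 10 lacked a p, against 8.03% of those with a mean of at least 100. RNA of ovary and of midgut present in unequal amounts between the libraries of a strain stays open. The test compared the SE of members with a p to those of genes with a p and the same mean. The median ratio was 1.30 for 6 of 32 ovary genes (95% bootstrap interval 0.82 to 1.91). It was 1.41 for 37 of 69 midgut genes (1.25 to 1.54). Neither interval lay wholly above the 1.5 set for the test. The test cannot decide the question, because a missing p goes with a large SE. Leaving out members without a p thus tends to leave out the large SE that the explanation predicts. Over all members the ratios were 3.61 (2.43 to 4.09) for ovary and 1.82 (1.52 to 2.22) for midgut. This measure was chosen first and then replaced because a large SE and a missing p go together in other lists too. The ratio was 2.37 for the mitochondrial genome, 2.00 for Bomanin genes, 1.75 for antimicrobial peptide genes and 1.66 for heat-shock genes. For testis genes it was 0.966. A difference of ovary RNA between the strains stays open, as 62.5% of ovary members had a negative fold change and large SE would hide a shift; which libraries carried the RNA, and how many ovary-list genes heads and thoraxes also express, was not analysed here.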

How the results depend on the processing

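Of the alternatives, the minimum of 5 CPM and the 2-fold threshold for arms were set before the data were examined, and the others were chosen after seeing the data. No paired analysis was possible because the table has no column for any library. For the same reason the planned edgeR, DESeq2 and voom fits, other scalings, each library left out in turn, other splits of the samples, an estimated correlation, fry, the floors for strain-limited genes and the pseudocounts were not run; the deposited table itself applies no filter on low counts. Over 5 alternatives the number of entries that differed ran from 3031 to 4127, against 3939. The number that differed by at least 2-fold was 245 with a mean of at least 5 CPM, against 695 without that minimum. It fell by a larger share than the tested entries, which went from 13395 to 8271. Most of the 695 entries thus had a mean under 5 CPM. Among 3194 entries that passed with that minimum, 3065 had also passed without it. The number of lists that differed was 9 with matched random lists, against 4, and from 3 to 6 otherwise. Matched lists were drawn gene by gene, with no correlation between members. Their p-values may be too small where members of a list vary together. Cuticle genes, not called in the main test, were higher in Oregon R with the minimum of 5 CPM (adjusted p = 0.0436) and higher in Dahomey against matched lists (adjusted p = 0.00213); antimicrobial peptide genes were higher in Dahomey against matched lists (adjusted p = 0.00128). The cause was not tested. Phototransduction genes passed by ranks and against matched lists, odorant-binding protein genes with the minimum of 5 CPM and against matched lists, and hemocyte (adjusted p = 0.0128) and UDP-glycosyltransferase genes (adjusted p = 0.0164) against matched lists, all higher in Oregon R. The ribosomal protein call held in all 5 list alternatives; those of midgut and P450 genes were lost with ranks, midgut also against matched lists, and that of oxidative phosphorylation genes with a correlation of 0.05 (adjusted p = 0.203). Shares by arm differed with the minimum of 5 CPM (chi-square p = 0.000143), and the cause was not tested. The 104 named genes above that minimum kept their side of the threshold. The depth of each library is unknown, so what depth limits was not tested.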

Other observations

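The test of scaling was chosen after its value was seen; the genes named here were chosen after their values were seen. The eye-colour transporter gene white (w) had a log2 fold change of -5.44 ± 0.20 and the body-colour gene ebony (e) -1.45 ± 0.19, both without a p-value, in the authors' deposited table. The labels give no eye colour for either strain. The clock genes per, tim and vri, whose transcripts cycle over the day, had log2 fold changes of 0.52 ± 0.36, 0.57 ± 0.38 and 0.32 ± 0.30 and no p-value in the authors' deposited table, whereas cyc, which does not cycle, had an SE of 0.051. The flight-muscle actin gene Act88F had 1.25 ± 0.16 and the odorant-binding protein gene Obp99a -2.04 ± 0.15, again without a p-value in the authors' deposited table. The attacin genes AttC and AttA had 0.90 ± 0.42 and -1.79 ± 0.42, and the larval storage protein genes Lsp2 and Lsp1beta -1.91 ± 0.39 and -1.40 ± 0.41, with no p-value for any of them in the authors' deposited table.

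Genes that differed formed runs of neighbours in 1 direction. The longest run held 8 genes higher in Oregon R on arm 2R, among them both amylase genes, Amy-p and Amy-d, and GstS1. A run of 7 genes higher in Dahomey on arm 3L held GstO3, GstO2, GstO1, se, foi and ergic53, and a run of 6 on arm 3R held Unc-115b, p24-2, Unc-115a and eca. Another 5 in Oregon R's direction were the odorant-binding protein genes Obp57c, Obp57b and Obp57a with CG13426 and GNBP-like3, and 5 more on the same arm were the tetraspanin genes Tsp42Ej, Tsp42Ek, Tsp42El, lbm and Tsp42En. Separately, 2 gene IDs stood on rows that passed in opposite directions: nemy, a gene with a role in memory, at 0.56 ± 0.056 and -0.56 ± 0.069, and Svil at 0.38 ± 0.078 and -0.53 ± 0.066 in the authors' deposited table.

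Over all adjacent genes that did not overlap and both differed, 62.2% of 1111 pairs shared a direction, against 50.1% with calls shuffled over positions within arms. Reads shared by overlapping genes are argued against as the whole cause, since 58.1% of 389 pairs at least 1000 bases apart shared a direction, above the range of 45.3% to 55.3% that holds 95% of 1000 permutations (permutation p = 0.001, the smallest they can give). Of 352 pairs that did not overlap and had names of different families, 61.1% shared a direction (permutation p = 0.002). Tandem copies of a family stay open, since names alone do not show relatedness. For example, se lay in a run with GstO genes and lbm with other tetraspanin genes. As a hypothesis, sequence differences between the strains that act on several neighbouring genes may contribute; this was not tested. Reads that map less well where 1 strain differs from the reference genome, and genes missing from 1 strain, were not analysed here and stay open.

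The opposite shifts of ribosomal protein genes (median 0.29) and oxidative phosphorylation genes (median -0.19) were weighed as a second pattern, although 44 of 89 oxidative phosphorylation genes did not pass and that list's call was lost with a preset correlation of 0.05 (adjusted p = 0.203). The gap between the medians was 0.47 (95% bootstrap interval over list members 0.38 to 0.51). This gap cannot test scaling between libraries, because scaling moves all genes alike and cancels from any difference of medians. The lists were also paired because these data had shown them shifted in opposite directions. Where 0 lies between the medians may depend on scaling, and this stays open. Transcript length is argued against, since the list's median lay 0.29 above that of lists matched on exon length and mean for ribosomal protein genes, and for oxidative phosphorylation genes the difference was -0.18, both outside 95% of 10000 matched lists. For the oxidative phosphorylation part, a lower share of muscle in the Dahomey samples is argued against only where all muscle types fall alike. Muscle genes would then fall by at least about as much, and their median was 0.14 (95% bootstrap interval -0.079 to 0.20). Of the 33 members, 8 were lower in Dahomey and 12 were higher, among the latter the cytoplasmic myosin light chain gene Mlc-c, which does not mark muscle. A change in flight muscle alone stays open. There TpnC4 had -0.77 ± 0.10 and Act88F, without a p-value, 1.25 ± 0.16 in the authors' deposited table. A difference between the strains in these pathways may remain as a hypothesis, next to differences in RNA quality or handling, which were not analysed here.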
